A study of Mus musculus with 11 samples.

How the data were processed

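RNA of liver cells selected with EpCAM beads was sequenced in 11 mice, 4 Control, 4 DDC and 3 R15, from stranded mRNA libraries per the labels' protocols. The authors deposited 1 table of FPKM per gene and library with gene IDs, names, types, lengths and coordinates. Genome build mm10 is given per the submitters' processing notes, while the aligner, the counting tool and the gene models' release are not given in the sources used here. The table's FPKM values, as deposited, could be turned back into whole reads for 100% of nonzero values within a tolerance of 0.001 (largest distance 2.3e-10). This took the smallest nonzero value of a library as 1 read and the gene length as the given length plus 1, both inferred from the values and not stated in the table. These reads were used for the depth and for 1 alternative test, not for the main test. Library totals were 70373265, 57728932, 69205068 and 67170313 reads for Control 1 to 4, 72929107, 64863658, 49339240 and 56298085 for DDC 1 to 4 and 69328035, 63854476 and 64594814 for R15 1 to 3. Values of FPKM 0.9 to 1.1 rested on a median of 122.5 reads. Of the 43346 gene IDs, 42462 were found in GENCODE M21. The 37 mitochondrial genes were at 0 in every library, so a mitochondrial share could not be checked. Of the genes tested, 62 shared a symbol with another, and 2 entries of the table had no name.

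The value tested was log2(FPKM + 1), which understates the change of low genes. Genes with FPKM of at least 1 in at least 3 libraries were tested, 15264 in all. All 11 libraries entered 1 linear model with the 3 groups in limma 3.58.1 (R 4.3.3), with empirical Bayes variances that follow the mean. The 2-sided p was adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The 3 comparisons were DDC against Control, R15 against Control and R15 against DDC. No pairing or replicate term was used, since each library has its own mouse. Genes passing in DDC and R15, each against Control, were counted with the same direction, beside the number that independent lists would share, 50 simulations of unchanged groups with shared controls and the 6 splits of the Control libraries. Genes that moved back were those passing in DDC against Control and, in the opposite direction, in R15 against DDC.

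Comparisons, tests, the rule for named genes, 31 gene lists and most alternatives were fixed before the data were examined. The lists covered NF-Y subunits, the cell cycle, G1 cyclins, p53 targets, PRC2 and DNA methylation, the reactive secretome, ductular markers, YAP, Notch, heme, NRF2, the unfolded protein response, cholesterol, glycolysis, duct transport, tight junctions and cilium, antigen presentation, interferon, immediate early genes and markers of 11 cell types. The ductular list shares 4 genes with the cholangiocyte list, the duct transport list 2 and the tight junction list 3, and the p53 and unfolded protein lists share 1. Lists of pancreatic acinar genes (17) and gastric mucous genes (7) were added after the values were seen. Lists were tested with limma camera (preset correlation 0.01), adjusted over the 31 lists, and their members were counted as adjusted over all genes and over the list alone. Only members among the genes tested entered. This left out most of the neutrophil, T and NK cell, stellate cell and fibroblast, and erythroid lists. Named genes were, per comparison, the 5 largest rises and 5 largest falls among genes passing with mean FPKM of at least 5 in the higher group, no overlap between groups and a symbol that is not a clone name; for each list described, the 3 members with the smallest p; and a fixed set of 18 genes that includes the NF-Y genes.

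Alternatives were pseudocounts of 0.1 and 5, no filter and a filter at FPKM 5, median-of-ratios scaling, rescaling to one total, quantile normalization, robust eBayes, array weights, only the 2 groups compared, an absolute log2 change of at least 1, an adjusted p under 0.01, the replicate number as a block, each library left out, and camera with an estimated correlation or fry for lists. Chosen after seeing the data were limma voom on the whole reads, protein-coding genes alone, the pancreatic score as a covariate, Control 1 and Control 3 left out, and the 5 libraries with pancreatic transcripts left out.

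The tests were run on simulated data first, with 50 genes changed per fold. At folds of 1.25, 1.5, 2 and 4 the recovered share was 46%, 88%, 100% and 100% for DDC against Control (15001 genes, 4 others called), 42%, 78%, 98% and 100% for R15 against Control (14995 genes, 11 others) and 48%, 86%, 100% and 100% for R15 against DDC (14993 genes, 8 others). In each of them a changed list was called and 0 of 30 random lists were, by limma camera. The simulated genes varied independently of each other, with no differences in cell mix. False calls of lists whose genes vary together could therefore not appear. All simulated groups had the same spread, while the mean log2 variance in the data was 0.109 in Control, 0.0405 in DDC and 0.0994 in R15. False calls from 1 error estimate shared by groups of unlike spread could not appear either. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. A search of promoters for the CCAAT box was left out, since no genome sequence was at hand.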

Results

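RNA was sequenced from liver cells caught with beads against EpCAM, an epithelial surface protein, which the labels name as cholangiocytes, the cells that line the bile ducts. The 11 libraries came from male C57BL/6 mice aged 14 to 16 weeks, with 1 mouse per library. There were 4 Control mice on chow, 4 DDC mice fed for 10 days with the DDC diet, which blocks heme synthesis and causes cholestatic liver injury in mice, and 3 R15 mice returned to chow for 15 days after 10 days of the diet. The table gave FPKM for 43346 genes. Whole reads recovered from it came to between 49339240 and 72929107 per library, and a value near FPKM 1 rested on a median of 122.5 reads. After the filter on low values 15264 genes were tested, 12959 of them protein-coding. The first principal component held 60.5% of the variance and set the 4 DDC libraries apart from all others, and the second held 13.1%.

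Cholangiocyte genes were abundant in all groups. Epcam, the protein the beads bind, stood at 290 ± 24.2 FPKM in Control (SD, n = 4), 406 ± 31.9 in DDC (SD, n = 4) and 294 ± 9.19 in R15 (SD, n = 3). Spp1, which encodes osteopontin, stood at 7570 ± 1491, 8569 ± 410 and 7972 ± 555 FPKM in the same order, with no difference past the threshold in any comparison. The keratin gene Krt19 stood at 470 ± 164, 431 ± 33.3 and 289 ± 54.2 FPKM and passed in none, at -0.06 ± 0.23 on the log2 scale for DDC against Control, -0.65 ± 0.24 for R15 against Control and -0.59 ± 0.24 for R15 against DDC. Krt19 passed for R15 against Control without Control 2 (-0.85), and for R15 against DDC without Control 1 (-0.59), Control 2 (-0.59) or R15 2 (-0.72). Transcripts of other cells were present too. Alb, the hepatocyte gene for albumin, stood at 2773 ± 302 FPKM in Control, 1028 ± 222 in DDC and 1731 ± 281 in R15. A list of 17 digestive enzyme genes of pancreatic acinar cells, put together after the values were seen, took 1.14% of the reads in Control 1, 0.301% in Control 2, 0.133% in Control 3, 0.132% in DDC 1 and 0.183% in R15 3. It took at most 0.00125% in each of the other 6 libraries. Control 3 also held 703997 reads of gastric mucous genes, where the other libraries held 2840 to 6791. All 37 mitochondrial genes were listed at 0 in every library.

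**Figure D1:**
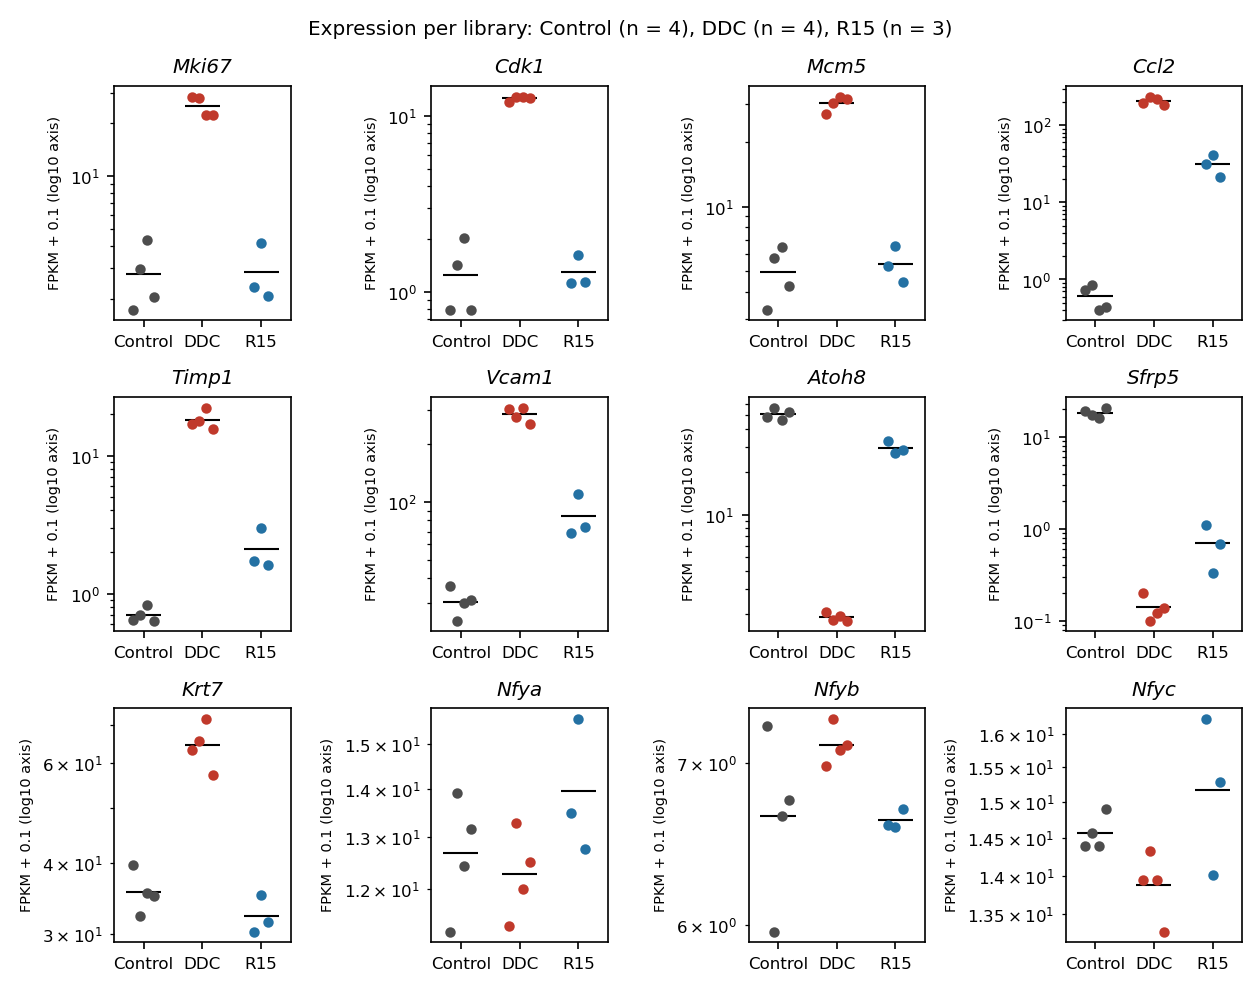
FPKM per library for 12 genes named in the text, on a log10 axis after adding 0.1, with 1 point per library and a bar at the group mean. Mki67, Cdk1 and Mcm5 were higher in all 4 DDC libraries than in any Control or R15 library, Ccl2 and Vcam1 stayed above every Control library in R15, and Sfrp5 stayed below. The Nfyc values were lower in all 4 DDC libraries than in any Control library, by little.

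The first comparison, DDC against Control, asks what 10 days of the diet did to these cells. The tested genes of DNA replication and of mitosis, and most of those of the cholangiocyte secretome list, were higher. Mki67, the standard marker of cycling cells, stood at 2.66 ± 1.17 FPKM in Control (SD, n = 4) and 25.2 ± 3.40 in DDC (SD, n = 4), a log2 fold change of 2.88 ± 0.23 (SE; limma adjusted p = 3.2e-06; ENSMUSG00000031004, mm10 chromosome 7, 135689788 to 135716379). Ccl2, the chemokine that draws monocytes, had the largest rise among the genes picked by the fixed rule, from 0.506 ± 0.218 to 207 ± 24.2 FPKM (log2 fold change 7.11 ± 0.18). Atoh8, a transcription factor gene, fell from 51.1 ± 4.48 to 1.79 ± 0.131 FPKM (-4.22 ± 0.07), and Sfrp5, a secreted inhibitor of Wnt ligands, fell from 18.3 ± 2.18 to 0.0399 ± 0.0435 FPKM (-4.21 ± 0.14). Of the 15264 genes tested with limma, 9981 (65.4%) changed, 5112 higher and 4869 lower. Counts of list members in this comparison are to be read beside this share. Of all genes that changed, 1202 of the higher and 600 of the lower ones did so by at least 2 times. The split moved with the scaling, being 4162 higher and 5518 lower with each library rescaled to one total, 4652 and 5309 with quantile normalization, and 5009 and 5023 with median-of-ratios scaling. In 9362 genes no DDC library overlapped a Control library, where chance gives 2.86% of genes. Next to Ccl2, the largest rises by that rule were those of Gpnmb (4.96 ± 0.51), Cpe (4.64 ± 0.11), Tgfbi (4.61 ± 0.34) and Lyz2 (4.59 ± 0.45). Gpnmb and Lyz2, the macrophage lysozyme gene, are abundant in macrophages, and Cpe encodes carboxypeptidase E. The largest falls next to those of Atoh8 and Sfrp5 were in the immunoglobulin variable genes Igkv6-23 (-4.72 ± 0.69), Igkv14-126 (-4.33 ± 0.92) and Igkv8-27 (-3.72 ± 0.70), whose reads can be split between near-identical family members and are uncertain. Ccl2 (ENSMUSG00000035385; mm10 chromosome 11, 82035571 to 82037453) overlaps the gene model Gm17268, and the counting's strand setting is not given in the sources used here.

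All 35 tested genes of DNA replication and S phase were higher in DDC (35 adjusted over the list alone), among them Rrm2, a subunit of ribonucleotide reductase, at 1.83 ± 0.313 against 12.7 ± 0.873 FPKM (2.28 ± 0.11), the origin licensing gene Cdc6 (1.55 ± 0.07), the histone chaperone gene Chaf1b (1.62 ± 0.06) and the helicase subunit gene Mcm5 (2.45 ± 0.17). All 34 tested genes of G2 and mitosis were higher as well (34 adjusted over the list alone). Examples were Anln, a protein of the cleavage furrow (2.37 ± 0.10), Prc1 of the central spindle (2.30 ± 0.11), Tacc3 (1.95 ± 0.09), Top2a (2.48 ± 0.18), Ccnb1 (2.09 ± 0.15) and Cdk1 (2.69 ± 0.16). Both lists passed the limma camera test with its preset correlation, at adjusted p = 1.4e-15 and 4.1e-15. These calls were lost at adjusted p = 0.56 and adjusted p = 0.69 with an estimated correlation, the ranges of the camera adjusted p over all alternatives being 2.5e-24 to 0.56 and 1.1e-22 to 0.69; further ranges are given alike. Among p53 targets and cell cycle inhibitors, 14 of 18 were higher and 2 lower (14 and 2 adjusted over the list alone), with Cdkn1a, the inhibitor p21, at 11.4 ± 3.92 against 37.3 ± 3.71 FPKM (1.68 ± 0.23), Tnfrsf10b at 1.02 ± 0.07 and Bax, which promotes apoptosis, at 0.97 ± 0.07 (camera adjusted p = 0.0024, and adjusted p = 0.56 with an estimated correlation, range 7.9e-06 to 0.56). The lower count was 1 without Control 2, Control 4, DDC 3 or DDC 4. Cdkn2a, the gene of p16 and p19ARF, lay under the filter and was not tested, at 0.153 ± 0.0503 FPKM in Control (SD, n = 4), 0.756 ± 0.130 in DDC (SD, n = 4) and 0.228 ± 0.151 in R15 (SD, n = 3).

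Of the list of PRC2 and DNA methylation maintenance genes, 9 of 12 were higher and 1 lower (9 and 1 adjusted over the list alone; camera adjusted p = 0.011, and adjusted p = 0.56 with an estimated correlation, range 5.9e-04 to 0.56). Uhrf1, which brings the maintenance methyltransferase to replicated DNA, rose by 3.22 ± 0.16, the helicase gene Hells by 2.30 ± 0.10, Dnmt1 by 0.84 ± 0.06 and Ezh2, the PRC2 methyltransferase, by 0.88 ± 0.08 on the log2 scale. The cell cycle lists rose in the same libraries, and whether the rise of this list was separate from theirs was not tested. The 3 subunits of NF-Y, the CCAAT-binding factor that the series title names, did not pass the threshold. Nfya (ENSMUSG00000023994; mm10 chromosome 17, 48386885 to 48409906) stood at 12.6 ± 1.13 FPKM in Control and 12.2 ± 0.819 in DDC, a log2 fold change of -0.04 ± 0.08 with a 95% interval from -0.21 to 0.13. Nfyb (ENSMUSG00000020248; chromosome 10, 82748701 to 82764144) stood at 6.56 ± 0.532 and 7.02 ± 0.133 FPKM (0.09 ± 0.05, 95% interval from -0.02 to 0.20), and Nfyc (ENSMUSG00000032897; chromosome 4, 120757438 to 120831572), which overlaps a microRNA gene, at 14.5 ± 0.243 and 13.8 ± 0.433 FPKM (-0.07 ± 0.04, 95% interval from -0.17 to 0.03). The limma count for the NF-Y list was 0, with 0 genes at an unadjusted p under 0.05 and 0 by limma voom. Without Control 1 it was 1, Nfyb at 0.13. In each library of DDC, Nfyc lay below every Control library. These are transcript levels, and NF-Y protein or binding was not measured here.

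Genes that reactive cholangiocytes secrete or display formed another group that moved far. Of the secretome list, 23 of 27 were higher in DDC and 3 lower (23 and 3 adjusted over the list alone; camera adjusted p = 4.5e-05, and adjusted p = 0.56 with an estimated correlation, range 7.7e-07 to 0.56). Timp1, an inhibitor of matrix metalloproteases, rose from 0.604 ± 0.0904 to 18.0 ± 2.87 FPKM (3.56 ± 0.14), while Vegfa, the endothelial growth factor, fell from 161 ± 23.3 to 34.8 ± 0.911 FPKM (-2.16 ± 0.10). Macrophage markers moved with this list, at a median log2 fold change of 2.35. Among ductular reaction and progenitor markers 8 were higher and 5 lower of 17 (9 and 5 adjusted over the list alone; camera adjusted p = 0.26). The mean log2 value of the ductular list was 6.23 to 6.31 in the DDC libraries and 5.40 to 5.80 in the Control libraries. With fry, by which 22 lists passed, the ductular list had adjusted p = 3.6e-06. The laminin gene Lamb3 rose by 2.08 ± 0.09 and the integrin gene Itgav by 1.78 ± 0.08 on the log2 scale. Sox9, a transcription factor of the biliary lineage, fell from 104 ± 16.1 to 48.2 ± 1.70 FPKM (-1.08 ± 0.10). Krt7 rose by 0.84 ± 0.08 and Epcam by 0.48 ± 0.08 on the log2 scale. The cholangiocyte marker list as a whole went both ways, with 9 higher and 7 lower of 20 (9 and 7 adjusted over the list alone). Tspan8 rose by 1.13 ± 0.08 on the log2 scale.

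Of the bile duct transport and secretion list 9 of 16 were lower and 2 higher (9 and 2 adjusted over the list alone; camera adjusted p = 0.12); 4 were higher without Control 1. The export pump gene Abcb1a stood at 40.4 ± 2.44 FPKM in Control and 13.3 ± 0.739 in DDC (-1.54 ± 0.06), the glucose carrier gene Slc5a1 at -1.06 ± 0.12 and Ggt1 at -0.55 ± 0.07 on the log2 scale. Of the tight junction and cilium list 11 of 19 were lower and 5 higher (11 and 5 adjusted over the list alone; camera adjusted p = 0.33), with a median log2 fold change of -0.25 and a mean of 0.05. The claudin genes Cldn4 (2.83 ± 0.14) and Cldn1 (1.79 ± 0.11) rose, and the polycystin gene Pkd2 fell (-0.80 ± 0.07). Notch pathway genes were lower in 8 of 16 and higher in 4 (8 and 5 adjusted over the list alone; camera adjusted p = 0.39), with Dtx1 at -1.44 ± 0.09, Jag2 at -0.77 ± 0.09 and the receptor gene Notch1 at -0.76 ± 0.09. YAP and TEAD targets went both ways, 10 higher and 7 lower of 21 (10 and 8 adjusted over the list alone; camera adjusted p = 0.94), with Rbms3 at -1.29 ± 0.09, Crim1 at -0.75 ± 0.06 and Asap1 at 0.80 ± 0.08.

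Markers of other cell types moved in different directions under the diet. Of the macrophage and Kupffer cell list 10 of 14 were higher and 1 lower (10 and 1 adjusted over the list alone; camera adjusted p = 0.022, and adjusted p = 0.85 with an estimated correlation, range 7.3e-04 to 0.85), with the complement gene C1qb at 4.15 ± 0.52 on the log2 scale and Csf1r at 1.28 ± 0.15. The lower count was 0 without Control 3, Control 4 or DDC 2. Of the dendritic cell list 6 of 7 were higher (6 adjusted over the list alone; camera adjusted p = 0.027, and adjusted p = 0.76 with an estimated correlation, range 0.0014 to 0.76), with Flt3 at 2.02 ± 0.15 and Itgax at 2.65 ± 0.31. Neutrophil markers were higher in 3 of the 4 tested (3 adjusted over the list alone, camera adjusted p = 0.12), while most members of the neutrophil list were not among the genes tested. S100a8 stood at 0.684 ± 0.683 against 23.6 ± 5.80 FPKM (3.92 ± 0.28) and S100a9 at 3.74 ± 0.27. Endothelial markers were lower in 11 of 12 (11 adjusted over the list alone; camera adjusted p = 0.010, and adjusted p = 0.85 with an estimated correlation, range 5.9e-04 to 0.85), with the VEGF receptor gene Kdr at 24.4 ± 16.8 against 2.42 ± 1.34 FPKM (-2.71 ± 0.54) and Ptprb at -2.78 ± 0.51. B and plasma cell markers were lower in 5 of 7 (5 adjusted over the list alone; camera adjusted p = 0.12), with Mzb1 at -1.34 ± 0.21. Hepatocyte markers went both ways, 6 higher and 6 lower of 20 (6 and 6 adjusted over the list alone; camera adjusted p = 0.87), with a median of 0.11, a mean of -0.08 and a test pointing down, or up with each library rescaled to one total. Alb fell (-1.45 ± 0.17). Rgs5, a pericyte and stellate cell marker, rose from 37.5 ± 13.7 to 452 ± 37.9 FPKM (3.61 ± 0.20). Its list of stellate cell and fibroblast markers had 1 higher and 1 lower of the 5 tested (camera adjusted p = 0.87), with most of its members not tested.

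**Figure D2:**
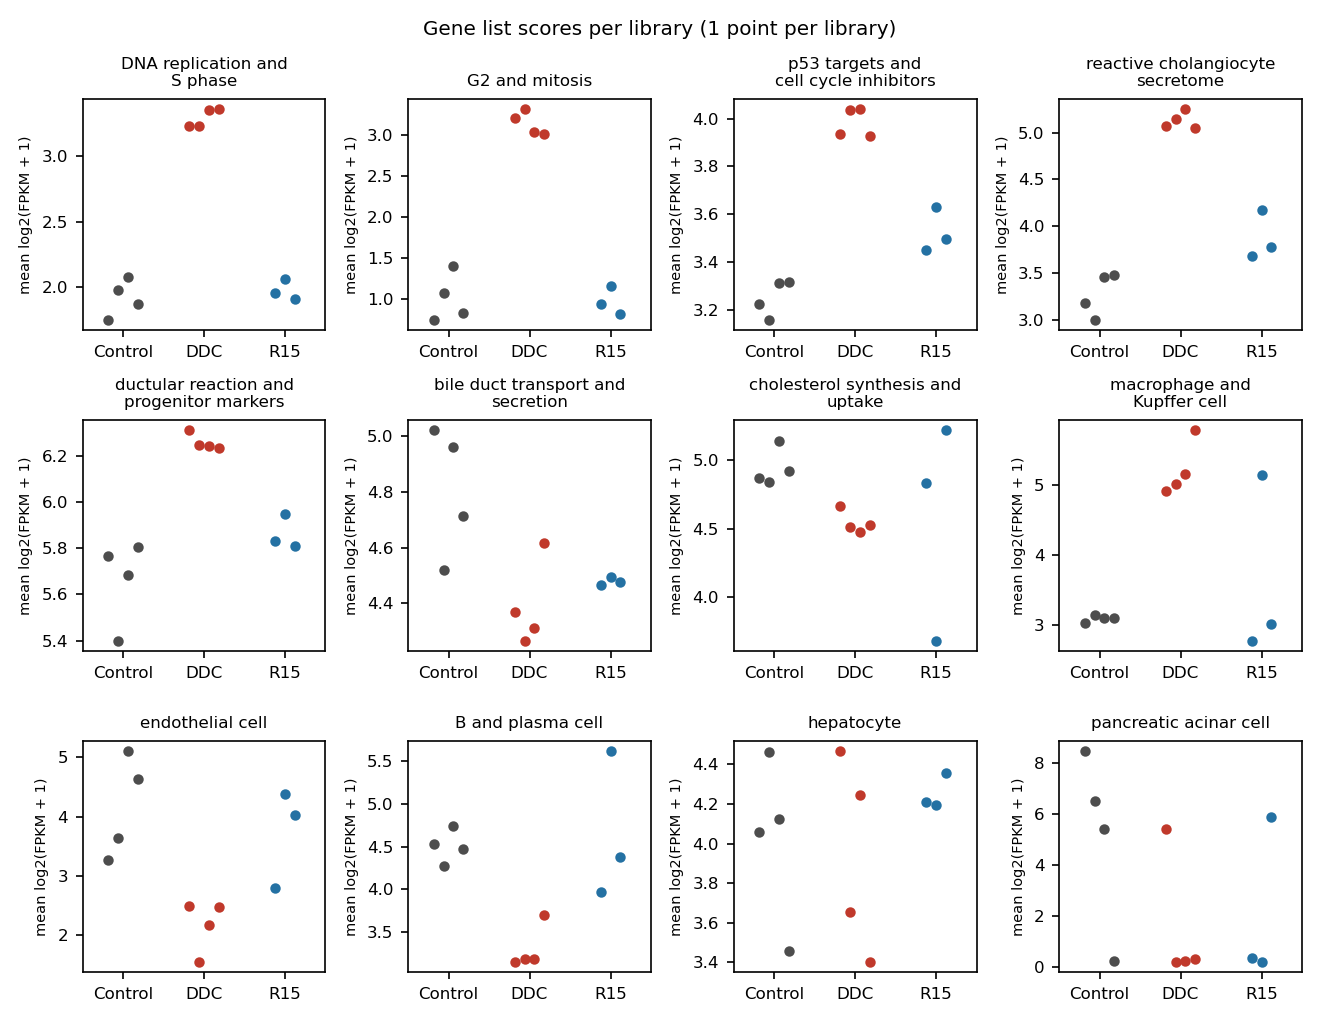
Mean log2(FPKM + 1) of the tested members of 12 gene lists in each library, with 1 point per library, grouped as Control, DDC and R15. The cell cycle lists were high in the 4 DDC libraries, the macrophage list in the 4 DDC libraries and in R15 2, the cholesterol list was low in R15 2, and the pancreatic list was high in 5 libraries across the 3 groups.

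The comparison of R15 with DDC asks what changed once the diet had stopped for 15 days. Every tested gene of the 2 cell cycle lists fell. Mki67 stood at 2.76 ± 1.14 FPKM in R15 (SD, n = 3) against 25.2 ± 3.40 in DDC (SD, n = 4), a log2 fold change of -2.83 ± 0.25 (adjusted p = 1.2e-05). All 35 genes of DNA replication and S phase and all 34 genes of G2 and mitosis were lower in R15 (35 and 34 adjusted over the list alone), among them Rrm2 (-2.56 ± 0.12), Chaf1b (-1.56 ± 0.07), Anln (-2.50 ± 0.11) and Prc1 (-2.26 ± 0.12). The camera test gave adjusted p = 1.4e-18 for both lists, and adjusted p = 0.51 for both with an estimated correlation, with ranges over the alternatives of 7.8e-28 to 0.51 and 4.1e-27 to 0.51. Vtn, which encodes the plasma protein vitronectin, rose from 15.0 ± 5.23 to 177 ± 52.0 FPKM (3.48 ± 0.31), and Atoh8 from 1.79 ± 0.131 to 29.3 ± 2.98 FPKM (3.44 ± 0.08). In all, 9496 genes (62.2% of those tested) changed, 5099 higher and 4397 lower, with 540 and 890 past 2 times. Between the groups 10166 genes did not overlap, where chance gives 5.71%. With each library rescaled to one total, the split was 6172 higher and 3305 lower (4679 and 4825 with median-of-ratios scaling), and the median of all genes moved by 0.10 to 0.14 on the log2 scale.

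Other groups that had risen under the diet were lower in R15 than in DDC. Of the secretome list 19 of 27 were lower and 3 higher (19 and 3 adjusted over the list alone; camera adjusted p = 1.2e-04, and adjusted p = 0.51 with an estimated correlation, range 2.5e-06 to 0.51); 1 was higher without R15 1. Ccl2 stood at 30.9 ± 9.62 FPKM in R15 (-2.74 ± 0.19), Timp1 at -2.68 ± 0.16 and Vegfa at 2.01 ± 0.11 on the log2 scale. The p53 list was lower in 11 of 18 and higher in 2 (11 and 2 adjusted over the list alone; camera adjusted p = 0.015, and adjusted p = 0.51 with an estimated correlation, range 2.9e-04 to 0.51), with Bax at -0.89 ± 0.07. The PRC2 and methylation list was lower in 7 of 12 and higher in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.031, and adjusted p = 0.51 with an estimated correlation, range 0.0043 to 0.51), with Uhrf1 at -2.91 ± 0.17. Macrophage markers were lower in 8 of 14 (8 adjusted over the list alone; camera adjusted p = 0.031, and adjusted p = 0.86 with an estimated correlation, range 1.4e-05 to 0.86), with Lyz2 at -3.32 ± 0.49, and 12 were lower without R15 2, the R15 library with the highest macrophage score. The camera call was lost without DDC 4 (0.051), R15 1 (0.070) or R15 3 (0.071). Neutrophil markers were lower in 3 of the 4 tested (3 adjusted over the list alone, camera adjusted p = 0.048, and adjusted p = 0.70 with an estimated correlation, range 0.0048 to 0.70). Their camera call was lost without Control 1 (0.057), Control 2 (0.061), Control 3 (0.0505), Control 4 (0.051), DDC 4 (0.067) or R15 1 (0.068). Genes of the bile duct went both ways. Of the cholangiocyte list 7 of 20 were higher and 9 lower, with a median of -0.51 (7 and 10 adjusted over the list alone; camera adjusted p = 0.58), and of the ductular reaction and progenitor list 4 of 17 were higher and 9 lower (4 and 9 adjusted over the list alone; camera adjusted p = 0.19). Pkhd1, the fibrocystin gene, rose by 1.56 ± 0.14, Sox9 by 1.26 ± 0.11 and Onecut1 by 1.21 ± 0.10 on the log2 scale. Of the tight junction and cilium list 10 of 19 were higher and 5 lower (10 and 5 adjusted over the list alone; camera adjusted p = 0.41), and of the Notch list 8 of 16 were higher and 4 lower (8 and 4 adjusted over the list alone; camera adjusted p = 0.31). Endothelial markers were higher in 10 of 12 (10 adjusted over the list alone; camera adjusted p = 0.048, and adjusted p = 0.86 with an estimated correlation, range 0.0057 to 0.86); 6 were higher without DDC 2, 5 without R15 2 and 6 without R15 3. The camera call was lost without Control 2 (0.058), Control 4 (0.051), DDC 2 (0.084), DDC 3 (0.053), R15 2 (0.13) or R15 3 (0.089). The NF-Y genes stood at 0.17 ± 0.08 for Nfya, -0.09 ± 0.05 for Nfyb and 0.12 ± 0.05 for Nfyc. For this list the limma count was 0, with 1 gene at an unadjusted p under 0.05 and 0 by limma voom. Nfyc (adjusted p = 0.051) just missed the threshold, and it passed at 0.12 with the stricter filter, with robust eBayes and among protein-coding genes alone, at 0.13 with array weights, and at 0.17 without R15 2. Nfya passed at 0.18 with the pancreatic score as a covariate. With each library rescaled to one total Nfya was at 0.28 and Nfyc at 0.23, both past the threshold, while Nfyb was at 0.01.

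By the fixed rule, the largest rises from DDC to R15 were those of Chil4 (4.43 ± 1.70), Msmp (4.00 ± 0.19), Vtn, Atoh8 and the immunoglobulin gene Igkv3-2 (3.43 ± 1.15). Chil4, a chitinase-like gene with near-identical family members, passed at adjusted p = 0.043 and lost its call without Control 3 or any single DDC or R15 library, at 3.92 to 4.70 on the log2 scale. Igkv3-2 passed at adjusted p = 0.025 and lost its call without DDC 1, DDC 3, R15 1 or R15 2, at 2.76 to 3.34. Msmp, which overlaps Rgp1, was nearly silent in DDC, at 0.218 ± 0.224 FPKM. The largest falls were those of Gpnmb (-3.64 ± 0.55), Tgfbi (-3.48 ± 0.37), the neutrophil chemokine gene Cxcl5 (-3.37 ± 0.71), Wfdc18 (-3.35 ± 0.60) and the cyclin gene Ccnb2 (-3.34 ± 0.31).

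The comparison of R15 with Control asks what still differed 15 days after the diet. No gene of the 2 cell cycle lists passed the threshold. Mki67 stood at 2.76 ± 1.14 FPKM in R15 (SD, n = 3) and 2.66 ± 1.17 in Control (SD, n = 4), with a log2 fold change of 0.05 ± 0.25 and a 95% interval from -0.50 to 0.60; it stood at -0.03 with quantile normalization. Ccl2 was still at 30.9 ± 9.62 FPKM against 0.506 ± 0.218 (log2 fold change 4.37 ± 0.19; adjusted p = 4.5e-06), and Hp, the acute-phase protein haptoglobin, at 78.7 ± 14.7 against 12.6 ± 6.87 FPKM (2.66 ± 0.31). Sfrp5 remained low, at 0.603 ± 0.386 against 18.3 ± 2.18 FPKM (-3.61 ± 0.15). In all, 1463 genes (9.58% of those tested) passed in limma, 1048 higher and 415 lower, with 126 and 15 past 2 times. Between the groups 3250 genes did not overlap, where chance gives 5.71%. The split moved with the scaling. It was 682 higher and 707 lower with median-of-ratios scaling, 594 and 468 with quantile normalization, and 807 and 253 with each library rescaled to one total.

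The size of this count was sensitive to which libraries entered. It was 819 without Control 1, 938 without Control 3, 950 without DDC 2, 685 without R15 1 and 749 without R15 2, and 317 with only the 2 groups compared in the fit, where the DDC libraries, with the smallest spread, no longer enter the estimate of the error. With the pancreatic score as a covariate it was 571, and it was 511 with Control 1 and Control 3 left out and 10 with the 5 libraries that held pancreatic transcripts left out, which leaves 1 Control library; these 3 fits were chosen after seeing the data. The examples below passed the threshold whichever single library was left out, unless stated.

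Of the secretome list 10 of 27 were higher and 2 lower in R15 (10 and 2 adjusted over the list alone; camera adjusted p = 0.0035, and adjusted p = 0.80 with an estimated correlation, range 1.6e-04 to 0.80). The camera call was lost without Control 2 (0.056). Vcam1, the adhesion molecule that binds leukocytes, rose by 1.43 ± 0.17 and Timp1 by 0.88 ± 0.16 on the log2 scale. Without R15 2, where macrophage markers were high, 7 members were higher and 0 lower, 7 being the lowest count over single libraries left out. The lower count was 0 to 1 without any single Control library, without DDC 1, DDC 2 or DDC 3 and without any single R15 library. Of the ductular reaction and progenitor list 5 of 17 were higher and 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.65), with Itgav at 32.3 ± 0.241 against 16.1 ± 1.97 FPKM (0.97 ± 0.09) and Lamb3 at 0.84 ± 0.10; 2 were lower without Control 2. The claudin gene Cldn1 was higher (0.80 ± 0.12), as were the YAP targets Ccn1 (1.36 ± 0.18) and Gadd45a (0.36 ± 0.07), the Notch target Heyl (0.78 ± 0.12), the p53 target Plk2 (0.45 ± 0.09), the immediate early gene Jun (1.15 ± 0.18) and the pericyte marker Rgs5 (2.24 ± 0.21). The lists of the first 4 of these did not pass. Of YAP and TEAD targets 4 of 21 were higher (camera adjusted p = 0.13, range 0.025 to 0.83). In the Notch list 2 of 16 were higher (camera adjusted p = 0.97). Tight junction and cilium genes were higher in 2 of 19 (camera adjusted p = 0.87). Of the stellate cell and fibroblast list, which holds Rgs5, 1 of the 5 tested was higher (1 adjusted over the list alone, camera adjusted p = 0.77). Of the dissociation and immediate early list 2 of 17 were higher, with a median of 0.76 and 9 at an unadjusted p under 0.05 (2 adjusted over the list alone; camera adjusted p = 0.0053, and adjusted p = 0.83 with an estimated correlation, range 1.3e-05 to 0.83). The higher count was 3 without Control 2, 8 without Control 4, and 1 without Control 1, Control 3, R15 1, R15 2 or any single DDC library. The camera call was lost without Control 2 (0.057) or R15 2 (0.087). Of the p53 list 4 of 18 were higher (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.013, and adjusted p = 0.80 with an estimated correlation, range 6.8e-04 to 0.80), or 2 without Control 3, R15 2 or R15 3 and 1 without R15 1, and the camera call was lost without Control 2 (0.057) or R15 2 (0.061). Dendritic cell markers were higher in 3 of 7 (5 adjusted over the list alone; camera adjusted p = 0.034, and adjusted p = 0.83 with an estimated correlation, range 0.0031 to 0.83). This count was 1 without DDC 1 and 0 without Control 3, Control 4, DDC 2, DDC 3, R15 2 or R15 3. The camera call was lost without Control 2 (0.083), Control 3 (0.062), Control 4 (0.064), R15 2 (0.21) or R15 3 (0.052). Of the hepatocyte list 6 of 20 were higher (7 adjusted over the list alone; camera adjusted p = 0.82), with the fibrinogen gene Fgb at 2.52 ± 0.33, and Alb was lower at -0.69 ± 0.19 (adjusted p = 0.046). The Alb call was lost without any single Control or R15 library or DDC 2, DDC 3 or DDC 4, at -0.56 to -0.79. Serpina1a (1.91 ± 0.29), Serpina1b (3.18 ± 0.28) and Serpina1c (1.23 ± 0.20) are close copies and uncertain. The list's lower count was 2 (4 adjusted over the list alone), and 0 or 1 without any single library other than Control 4.

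Below the Control level in R15 were Tmod1, an actin-capping gene, at 4.30 ± 1.11 against 12.9 ± 1.84 FPKM (-1.41 ± 0.16), Hamp2, a hepcidin gene with a close copy (-1.27 ± 0.13), Lmcd1 (-1.25 ± 0.17), the cyclin gene Ccnd2 (-0.67 ± 0.11), Abcb1a (-0.44 ± 0.06) and the mesothelial markers Upk1b (-0.93 ± 0.11) and Upk3b (-0.98 ± 0.15). Pigr, the receptor that carries IgA into bile, stood at 72.6 ± 13.3 FPKM in R15 against 388 ± 103 in Control (-2.37 ± 0.49; adjusted p = 0.018), a call lost without R15 1 (-2.30) or R15 2 (-2.29). Of the bile duct transport list 3 of 16 were lower (4 adjusted over the list alone; camera adjusted p = 0.0012, and adjusted p = 0.50 with an estimated correlation, range 3.3e-04 to 0.50), and 1 was lower without R15 2. The immunoglobulin genes Igkv2-137 (3.35 ± 0.82) and Ighv14-1 (3.08 ± 0.35) were among the 5 largest rises, both uncertain for shared reads, and Igkv2-137 lost its call without Control 3, Control 4, DDC 1, DDC 2, R15 1 or R15 2, at 2.59 to 3.47. No gene of the 2 cell cycle lists or of NF-Y passed in limma or in limma voom. At an unadjusted p under 0.05 there were 2 higher and 1 lower genes of DNA replication and S phase, 0 of G2 and mitosis and 0 of NF-Y. The camera test of G2 and mitosis gave adjusted p = 0.15, with a median log2 fold change of -0.03, and passed without Control 1 (0.010), Control 4 (0.022) or R15 2 (0.0064). The S phase count was 1 without Control 2 or without R15 2. Log2 fold changes were 0.13 ± 0.08 for Nfya, -0.0026 for Nfyb and 0.05 ± 0.05 for Nfyc, with 95% intervals from -0.06 to 0.31, from -0.12 to 0.12 and from -0.05 to 0.16. The Nfyb change was 0.02 with each library rescaled to one total. Changes of Cdkn1a (0.07 ± 0.25), Sox9 (0.17 ± 0.11) and Krt7 (-0.14 ± 0.09) did not pass, and Epcam stood at 0.02 ± 0.08, or -0.03 with median-of-ratios scaling.

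Most of what the diet changed had moved back by day 15 on chow. Of the 5112 genes higher in DDC than in Control, 3953 (77.3%) were lower in R15 than in DDC, and of the 4869 lower genes, 4120 (84.6%) were higher, 8073 in all. Both comparisons use the same DDC libraries, which by itself makes genes appear to return. With the DDC libraries split into 2 and 2, so that each comparison had its own, the count was 6544 to 6749, or 75.6% to 79.4%. Of the genes changed by at least 2 times, 93.9% of the higher and 85.5% of the lower ones had moved back, and the median share of the change that remained was 22.8% and 17.7%. Genes still changed in the same direction in R15 numbered 676 higher and 316 lower, 992 together, where independent lists would share 351 and 132, or 483. Of these, 361 higher and 190 lower genes are also among the 8073 that moved back. Moving back thus does not mean reaching the Control level. Another 116 genes passed in opposite directions, or 13 to 966 with the Control libraries split into 2 and 2. Mki67 stood at 0.05 and Ccl2 at 4.37 against Control, from 2.88 and 7.11 under the diet. Shared Control libraries alone give a correlation of 0.470 between the 2 sets of log2 changes across genes and a covariance of 0.0204 in simulations of unchanged groups, against 0.526 and 0.139 observed, and genes are not independent replicates. With the Control libraries split into 2 and 2, the overlap was 344 to 1089 and the covariance 0.0836 to 0.131. The overlap was 618 without Control 1, 560 without R15 1 and 534 without R15 2, and 262 with only the 2 groups compared in each fit. There were 274 higher and 81 lower genes in R15 that had not passed in DDC; whether their 2 changes differ was not tested.

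**Figure D3:**
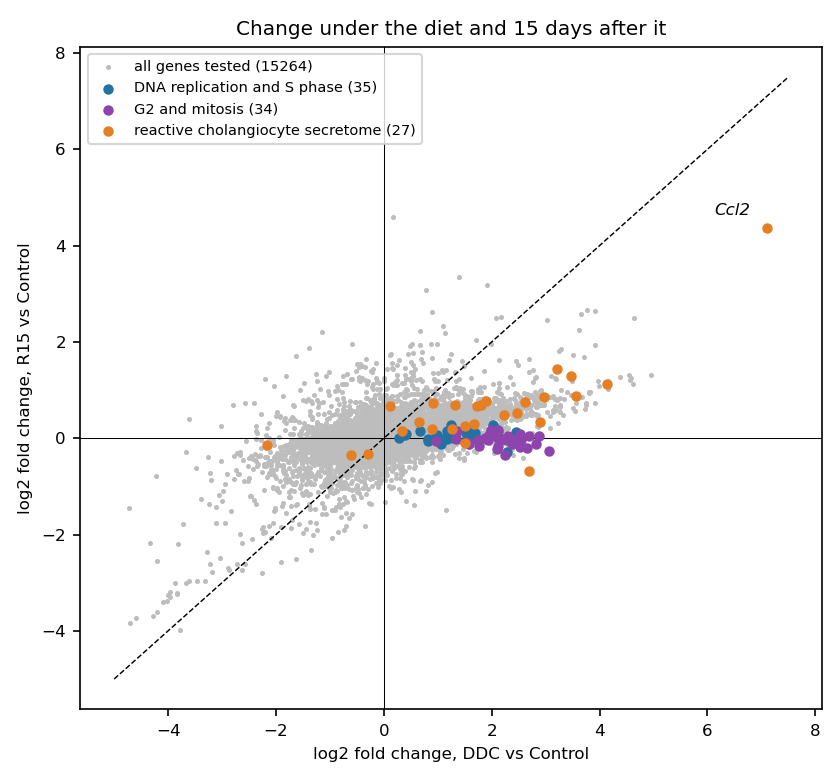
Log2 fold change of DDC against Control (x axis) and of R15 against Control (y axis) for the 15264 genes tested, with 1 grey point per gene and the genes of 3 lists in colour; the dashed line marks equal changes. The cell cycle genes lie right of 0 on the x axis and near 0 on the y axis, while part of the secretome genes, Ccl2 highest, lie above 0 on both.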

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

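The tests of the pancreatic transcripts, of the macrophage markers and of the excess of higher genes in R15 were chosen only after the result was seen. Groups of 4 libraries were searched for a library far from the other 3, with the gap over the range above 0.829, in the genes named, the list scores and the read totals; R15, with 3 libraries, was not searched. Of 280 groups of values searched, 17 held such a library, and chance gives about 1 in 20, or 14. On the log2(FPKM + 1) scale, they were Ccn1 in Control 2 (6.12, nearest other 5.77), Pigr in Control 2 (7.88, nearest 8.75), Igkv8-27 in Control 1 (4.29, nearest 5.40), Nr4a1 in Control 1 (2.70, nearest 3.34), Lmcd1 in Control 4 (4.79, nearest 4.23) and Tspan8 in Control 3 (8.23, nearest 8.01). In DDC they were Cldn4 in DDC 4 (7.65, nearest 8.01), Upk1b in DDC 4 (0.48, nearest 0.34), G6pdx in DDC 1 (5.24, nearest 5.30), Krt19 in DDC 3 (8.91, nearest 8.71) and Ifi44 in DDC 3 (1.04). Among list scores, they were NRF2 targets in DDC 2 (5.03, nearest 5.22), B and plasma cell markers in DDC 4 (3.71, nearest 3.18), dendritic cell markers in DDC 1 (3.01, nearest 3.23), mesothelial markers in Control 1 (2.65, nearest 2.98), pancreatic acinar genes in DDC 1 (5.42, nearest 0.32) and gastric mucous genes in Control 3 (10.57, nearest 3.21).

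Transcripts of pancreatic digestive enzymes were high in Control 1, Control 2, Control 3, DDC 1 and R15 3. The 17 genes kept nearly one ratio to each other, with correlations to Control 1 of 0.994, 0.979, 0.995 and 0.955 at the lowest, so pancreatic tissue or its RNA carried into the preparation is a candidate source. The share of reads of 0.132% in DDC 1 lay above the share in Control 4 and below those in the other Control libraries. DDC 2, DDC 3 and DDC 4 held at most 0.00123%. DDC 1 came close to Control 3, at 0.133%, and Control 4, at 0.00109%, was about as low as the rest of DDC. These shares therefore cannot decide whether the diet played a part. With the pancreatic score as a covariate, 571 genes passed in R15 against Control. Control 1, Control 2 and Control 3 held these transcripts but, within R15, only R15 3 did. The transcripts and the group therefore partly coincide in that comparison.

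Macrophage markers were high in the 4 DDC libraries and in R15 2. A lower share of cholangiocytes, with the mix of the other cells unchanged, would raise the markers of every other cell type alike. The endothelial list moved the other way, at a median of -2.11 on the log2 scale against 2.35 for macrophages. These values speak only to such an even dilution. A lower share together with a changed mix of the other cells stays open. RNA of macrophages as the whole cause of the higher secretome genes in R15 against Control is argued against by the 7 of 27 members that passed without R15 2, with a list median of 0.36, where macrophage markers had a median of -0.14. Without R15 2, 0 members of the macrophage list passed higher and 0 lower. Its member Csf1r still had 16549 reads in R15 1 and 14174 in R15 3, against 9786 to 12976 in the Control libraries. RNA of cells that express Csf1r as a part of the cause therefore stays open. More macrophages in the selected cells under the diet stay open and were not tested.

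In R15 against Control 71.6% of the genes passing were higher. The share was 49.1% with median-of-ratios scaling, 55.9% with quantile normalization and 76.1% with each library rescaled to one total. Median-of-ratios scaling sets the middle of the genes near 0, which by itself evens the share, so whether the scaling by total reads made the excess of higher genes stays open. The values of single genes named in the report kept their direction under median-of-ratios scaling, except for Epcam at -0.03, which did not pass. Whether total RNA per cell differed between the groups was not measured.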

How the results depend on the processing

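Chosen after seeing the data were voom, protein-coding genes alone, the pancreatic covariate and the 2 sets of libraries left out. Without each library in turn, the genes changed were 9202 to 10096 in DDC against Control, 685 to 2186 in R15 against Control and 8432 to 9686 in R15 against DDC, the overlap was 534 to 1352, the genes moved back 7367 to 8271, and the lists passing 8 to 11, 7 to 12 and 8 to 12. With an absolute log2 change of at least 1 the counts were 1802, 141 and 1430, the overlap 76 and the genes moved back 1197, by the stricter rule itself. In R15 against Control the count and the overlap were 317 and 262 with only the 2 groups in the fit, 346 and 267 at an adjusted p under 0.01, 693 and 516 with the replicate number as a block, 571 and 433 with the pancreatic covariate, 511 and 405 without Control 1 and Control 3, and 10 and 10 without the 5 libraries with pancreatic transcripts, where 1 Control library is left and is assumed to vary like the other groups. The lists passing, 9, 11 and 10, were 4, 7 and 3 at an adjusted p under 0.01, 22, 7 and 20 with fry and 0, 0 and 0 for limma camera with an estimated correlation; they were 14 in DDC against Control with no filter and 7 in R15 against Control without Control 1 and Control 3. 6 list results past the threshold with or without the alternative turned in direction, 5 of them in R15 against Control: antigen presentation and G2 and mitosis (adjusted p = 0.021 each) and interferon (0.61) without the 5 libraries, mesothelial cells with the filter at FPKM 5 (0.96), and cholesterol without R15 2 (0.82, and 0.0029 against DDC). Over single libraries left out, the cholesterol p ran from 1.0e-10 to 0.82 against Control and from 0.0029 to 0.995 against DDC. The cause was not tested except where fewer libraries or a stricter rule shows it.

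Of 4622 results for named genes under the alternatives 4471 stayed on the same side of the threshold, 129 lost the threshold, 22 gained it and 0 turned; of 2880 for lists the numbers were 2665, 139, 70 and 6. A turn was counted only where the result passed with or without the alternative, so a change of sign in a value that passed in neither stands among those on the same side. Such changes of sign included Mki67, Epcam, Fech and Nfyb among genes, and the tests of the hepatocyte and unfolded protein lists in DDC against Control with each library rescaled to one total, of the Notch, cholangiocyte and B and plasma cell lists in R15 against Control with median-of-ratios scaling, and of the S phase list there with quantile normalization. With the replicate block Nfya passed in R15 against DDC at 0.18. Equal replicate numbers did not pair the libraries: 3 of 10 pairs correlated above 0.1, and 1 of 11 libraries was closest to its own number. The edgeR and DESeq2 alternatives named at the start were not run although whole reads were recovered, since the deposited unit is FPKM; limma voom was run on those reads instead and called 9928, 1454 and 9422 genes. The CCAAT promoter tests were not run, for want of a genome sequence.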

Other observations

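The lists of NRF2 targets, heme, glycolysis, cholesterol and the unfolded protein response did not pass the camera test in DDC against Control. NRF2 targets, the genes of the oxidative stress response, were higher in 11 of 23 and lower in 4 in DDC against Control (11 and 4 adjusted over the list alone; limma camera adjusted p = 0.24), with G6pdx of the pentose phosphate pathway at 0.44 ± 0.04 and the glutathione transferase gene Gstm1 at -0.93 ± 0.09, and were lower in 13 of 23 and higher in 3 in R15 against DDC (14 and 3 adjusted over the list alone; camera adjusted p = 0.015, and adjusted p = 0.86 with an estimated correlation, range 6.9e-04 to 0.86). Heme and porphyrin genes, which the diet's block concerns, went both ways, 7 higher and 4 lower of 17 (7 and 4 adjusted over the list alone; camera adjusted p = 0.49), with a median of 0.05, or -0.04 with each library rescaled to one total. The mean log2 value of the heme list was 4.64 to 4.79 in the DDC libraries and 4.25 to 4.41 in the Control libraries. With fry, by which 22 lists passed, the heme list had adjusted p = 0.010. Uros (-0.56 ± 0.05) and Cpox (-0.63 ± 0.07), enzymes of heme synthesis, fell, and Blvra, biliverdin reductase, rose (0.70 ± 0.07). Fech, the ferrochelatase gene, stood at 0.05 ± 0.07, or -0.04 with each library rescaled to one total, and did not pass. Glycolysis genes were higher in 8 of 15 and lower in 3 in DDC (8 and 4 adjusted over the list alone; camera adjusted p = 0.56), with Gapdh at 0.80 ± 0.08 and Hk2 at 1.38 ± 0.24, and lower in 11 of 15 and higher in 2 in R15 against DDC (11 and 2 adjusted over the list alone; camera adjusted p = 0.031, and adjusted p = 0.86 with an estimated correlation, range 0.0050 to 0.86); 7 were lower without DDC 3 or R15 1, where the camera adjusted p was 0.063 without R15 1, and 1 was higher without DDC 1, DDC 3, DDC 4, R15 1 or R15 3. Cholesterol genes were lower in 7 of 24 and higher in 1 in DDC (2 and 1 adjusted over the list alone; camera adjusted p = 0.16), a count of 3 or 4 without any 1 Control or DDC library, 11 without R15 3 and 16 without R15 2 (camera adjusted p = 0.0038). The unfolded protein list was higher in 4 and lower in 5 of 19 (4 and 5 adjusted over the list alone; camera adjusted p = 0.94), and its test pointed down with each library rescaled to one total.

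Among immune and growth lists in DDC against Control, interferon response genes were lower in 8 of 20 and higher in 2 (8 and 2 adjusted over the list alone; camera adjusted p = 0.15), with Ifit2 at -0.69 ± 0.05 and Ifi44 at -0.94 ± 0.13. The higher count was 1 without Control 2, Control 4, DDC 1, DDC 3 or DDC 4 and 4 without Control 3, and without Control 4 the camera adjusted p was 0.044. Antigen presentation genes were higher in 5 of 14 (5 adjusted over the list alone; camera adjusted p = 0.56), with 3 lower without Control 4 and a median of 0.04, or -0.05 with each library rescaled to one total and -0.04 with quantile normalization. G1 cyclins and early growth factor genes were higher in 4 and lower in 7 of 15 (4 and 7 adjusted over the list alone; camera adjusted p = 0.49). Immediate early genes, which tissue dissociation can raise, were higher in 10 of 17 (10 adjusted over the list alone; camera adjusted p = 0.047, and adjusted p = 0.85 with an estimated correlation, range 0.0031 to 0.85), with Nr4a1 at 2.91 ± 0.25 and Ier3 at 1.91 ± 0.19; 5 were higher without Control 1, and the camera call was lost without Control 1 (0.085), Control 2 (0.088, with 1 member lower), Control 3 (0.067), DDC 2 (0.056), DDC 3 (0.057), DDC 4 (0.071) or R15 1 (0.055). Of the mesothelial list 3 of 4 were lower and 1 higher, of T and NK cell markers 1 of 3 was higher, and of stellate cell and fibroblast markers 1 was higher and 1 lower of 5 (3 and 1, 1, and 1 and 1 adjusted over the list alone), with camera adjusted p = 0.23, 0.56 and 0.87. Most members of the T and NK cell list and of the stellate cell list were not among the genes tested. The T and NK count was 2 without Control 1, R15 1 or R15 3, where 1 was lower without R15 1, and the stellate counts were 2 higher without Control 4 or R15 2 and 2 lower without R15 1. For erythroid genes the limma count was 0, with 0 higher and 0 lower at an unadjusted p under 0.05, and 1 was lower without R15 2.

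In R15 against Control, the camera test also passed for lists in which few or no members passed. For cholesterol synthesis and uptake the limma count was 0, with 1 lower at an unadjusted p under 0.05 (camera adjusted p = 4.0e-04, and adjusted p = 0.83 with an estimated correlation, range 1.0e-10 to 0.83), and without R15 2, which had a mean log2 value of 3.68 against 4.84 and 5.22 in the other R15 libraries, the adjusted p was 0.82. Glycolysis genes were lower in 3 of 15 (3 adjusted over the list alone; camera adjusted p = 4.0e-04, and adjusted p = 0.80 with an estimated correlation, range 1.3e-05 to 0.80), with 0 without R15 1 or R15 2 and 1 without Control 1, Control 3, Control 4, DDC 1, DDC 2 or R15 3. Of NRF2 targets 1 of 23 was higher and 1 lower (1 and 1 adjusted over the list alone; camera adjusted p = 5.1e-04, and adjusted p = 0.80 with an estimated correlation, range 4.3e-05 to 0.80). The higher count was 0 without Control 1, Control 3, R15 1 or R15 3. The lower count was 4 without Control 2 and 0 without any other single Control library, any single DDC library or R15 1. For interferon response genes the limma count was 0, as with limma voom, with 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.0045, and adjusted p = 0.83 with an estimated correlation, range 3.6e-05 to 0.83); 1 was lower without Control 4, and the camera call was lost without Control 1 (0.12) or R15 1 (0.061). For the unfolded protein list it was 0 as well, as with limma voom, with 1 higher and 2 lower at an unadjusted p under 0.05 (camera adjusted p = 0.034, and adjusted p = 0.87 with an estimated correlation, range 2.1e-04 to 0.94). There 1 was lower without Control 2 and 1 higher without R15 3, and the camera call was lost without Control 1 (0.26), Control 3 (0.11), R15 1 (0.47) or R15 3 (0.071). Of the mesothelial list 2 of 4 were lower (2 adjusted over the list alone; camera adjusted p = 0.023, and adjusted p = 0.80 with an estimated correlation, range 0.010 to 0.96), with the camera call lost without Control 2 (0.058).

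All 35 splits of the 8 libraries of DDC and Control into groups of the same size were run with only the 2 groups in the fit. Only the real split, 1 of 35, gave as many as its 9978 genes, and the highest other gave 20. For R15 against Control it was 1 of 35, with 317 genes and a highest other of 16. For R15 against DDC it was 1 of 35, with 9994 genes and a highest other of 1. A share of 1 of 35 is the smallest these splits can give. Splits that mix the groups put the group difference into the error, which lowers their counts. The test covers the 317 genes of this fit, not the 1463. In the first 2 comparisons the highest other parted the libraries with pancreatic transcripts from those without. Chance cannot be excluded for the number of lists passing camera. There 11 of 35, 16 of 35 and 29 of 35 splits passed as many as the real 11, 11 and 9. The highest others were 13, 19 and 15, so statements on lists rest on their members. Among all genes tested 65.4%, 9.58% and 62.2% passed in the same order of comparisons. Member counts near these shares say little about a list itself. Of 100 groupings of the 11 libraries, 1 gave an overlap as large as 992, the highest other being 3. For the genes that moved back, 2 of 100 gave as many as 8073. The other, with 8084, kept the 4 DDC libraries together and set Control 1, 2 and 4 as R15. That count follows the difference between DDC and all other libraries. Groupings that mix the DDC libraries with others lose this difference, so the count cannot decide on chance for the return. For the overlap of 992 the same limit holds, though the grouping with 8084 gave an overlap of 3.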
